A study of Mus musculus with 9 samples.

How the data were processed

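Gene expression was measured by RNA sequencing in 9 libraries of 3T3-L1 adipocytes expressing dCas9-KRAB, 3 each for the control, Dgat2-En4 and Pnpla2-En5 groups. Per the labels' protocols, cells were infected with lentivirus at a multiplicity of 100 for 12 h and selected with puromycin at 2 ug/ml. Differentiation was induced for 48 h with insulin at 10 ug/ml, dexamethasone at 2 ug/ml and IBMX at 0.5 mM in medium with 10% fetal bovine serum, and RNA was taken at day 7. Libraries were made from 1 ug of total RNA with polyA selection and the NEBNext Ultra RNA kit, per the labels' protocols. Whether the counting used strand is not given in the sources used here, so genes that overlap in exonic sequence, paralogs and short RNAs are reported as less certain.

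The deposited values are TPM (transcript abundance per 1000000), per the file headers. The authors used STAR 2.5.3a and featureCounts with the GRCm38 (mm10) genome, per the submitters' processing notes, which give no role or order for these tools and no gene annotation. TPM divides each gene's reads by its length and scales every library to a sum of 1000000, so a few abundant genes that take more of a library lower the TPM of all others. There were 9 tables for single libraries and 2 tables of the series that repeat the same columns, with a largest difference of 0.0. No column of per-sample values was left unused, and no table of the authors' own comparisons was used here. The tables list 55487 Ensembl gene identifiers. Symbols, coordinates and exon lengths came from GENCODE M21 on GRCm38, which named 55141 of them and left 346 unnamed.

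Depth was recovered from the TPM values. With the summed exon length of each gene, 54788 of 55227 identifiers that have a length (99.2%) came out within 0.02 of whole reads in all 9 libraries, and 16060 of the tested genes (98.5%). Counted reads were 18805059 to 31895210 per library. These sums include reads that appear to be counted at more than 1 copy of a sequence. Recovered reads served for depth, for the variance between replicates, for the reads given for short RNAs and for 1 alternative test. They never served for the main result. Replicate libraries correlated with Pearson's r of 0.976 to 0.983 across genes on the log2 scale, and the variance between them was 4.91 to 45.1 times that of Poisson sampling, so no pair differed by as little as sampling noise.

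The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend) on log2(TPM + 1). The fit held all 9 libraries with a mean per group, so the groups shared 1 estimate of the spread. Genes at 1 TPM or more in at least 3 libraries were tested, 16342 in all. The pseudocount of 1 understates the change of low genes. The p-values were adjusted by the Benjamini-Hochberg method and called at 0.05, and every adjusted p of a gene is from limma. The comparisons were each enhancer group against control and the enhancer groups against each other. For Dgat2 and Pnpla2 a two-sided exact permutation test was added, also in R. A change relative to all genes is the log2 fold change minus the median log2 fold change of all tested genes.

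Gene lists for adipocyte biology, metabolism, stress, signalling, other cell types and the neighbours of the targeted genes were written before the data were examined, as were the design, the alternatives to try and the rule for named genes. The 35 lists with at least 5 tested genes were tested with camera at its preset inter-gene correlation of 0.01, and again with the correlation estimated per list and with fry. Some lists share genes, so their results are not independent. Triacylglycerol synthesis holds Dgat2 and the adipocyte markers Agpat2, Gpd1 and Pck1. Lipolysis holds Pnpla2 and the markers Lipe, Plin1, Adrb3, Aqp7 and Fabp4. Sdha, Sdhb, Sdhc and Sdhd are in both oxidative phosphorylation and the tricarboxylic acid cycle. Lists of skeletal muscle, endothelial and epithelial markers had 2, 2 and 3 tested genes and were not tested. The rule named Dgat2 and Pnpla2, and per comparison the 8 higher and 8 lower genes of largest fold change with a mean of at least 5 TPM in the higher group and fully separated groups, leaving out gene models and pseudogenes. It also named the 4 members of each described list with the smallest adjusted p, and the neighbours past the threshold. Members that went against their list, and the genes nearest to Pnpla2 and Dgat2, were named beyond the rule, after their values were seen. Some genes that the rule names are not reported here.

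The alternatives were other pseudocounts (0.1 and 0.5), no filter or a filter at 5 TPM, trimmed-mean, median-of-ratios and quantile scaling, rescaling without the mitochondrial and the 20 most abundant genes, no trend, a robust variance, only the compared groups, other thresholds, the replicate number as a block, and leaving out each library. A voom fit on recovered reads, and the block together with median-of-ratios scaling, were added after seeing the data. The planned test on raw counts was not run because the tables used here hold TPM. Unchanged groups with shared controls were simulated 100 times. For this all 9 libraries were drawn around the control mean of each gene, with noise independent between genes.

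The pipeline was tested on simulated data with 200 of 16342 genes changed. At a log2 change of 1 it recovered 95.5% of changed genes for Dgat2-En4 against control, 95.5% for Pnpla2-En5 against control and 93.9% between the enhancer groups. At 0.5 it recovered 60.3%, 75.0% and 55.9%, with 9 false calls in each comparison. The 200 changed genes were drawn only from tested genes above a minimum TPM in control, not from all 16342. These rates therefore do not cover the low genes among those tested, where recovery was not measured. They also do not cover data in which as many genes change as were called here. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.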

Results

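Polyadenylated RNA was sequenced from adipocytes of the 3T3-L1 line, a mouse embryonic preadipocyte line that accumulates lipid when given a hormone cocktail. The cells carried dCas9-KRAB, a nuclease-dead Cas9 fused to a transcriptional repressor domain, which lowers the activity of the DNA its guide RNA points it to (CRISPR interference). There were 3 groups of 3 libraries each, all at day 7 of differentiation. The control group had the repressor with a control construct, for which the labels name no enhancer. The Dgat2-En4 group had guides against an enhancer of Dgat2, and the Pnpla2-En5 group had guides against an enhancer of Pnpla2. The comparisons address how repression of each enhancer changed the transcriptome. Values are TPM (transcript abundance scaled to the same sum in every library), given as mean ± SD over the 3 libraries of a group, and 16342 genes at 1 TPM or more in at least 3 libraries were tested. Reads recovered from the TPM values came to 18805059, 25427975 and 23526908 in the control libraries, 31895210, 22374998 and 25464205 in the Dgat2-En4 libraries, and 26365620, 29171252 and 28040610 in the Pnpla2-En5 libraries. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

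The control libraries were composed differently from the others. Mitochondrially encoded genes held 12.8 ± 2.15% of control TPM, 9.27 ± 0.28% in Dgat2-En4 and 8.20 ± 0.35% in Pnpla2-En5. Gm23935, annotated as a microRNA gene on chromosome 16, held 6.78 ± 2.62%, 3.72 ± 1.90% and 3.40 ± 0.52%. Protein-coding genes, leaving out the mitochondrially encoded ones, held 52.9998 ± 1.19%, 63.3 ± 1.12% and 65.1 ± 0.93%. The 20 most abundant genes held 31.1 ± 1.44%, 20.7 ± 1.57% and 19.3 ± 0.55%. On the TPM scale the median log2 fold change of all tested genes against control was 0.299 in Dgat2-En4 and 0.3002 in Pnpla2-En5, and it was 0.0034 between the enhancer groups. Changes of genes and gene lists are therefore given relative to that median unless stated otherwise. Calls of "rose" and "fell" are those of limma on TPM, and counts after median-of-ratios scaling, which brings the median near 0, stand beside them. Adiponectin in Dgat2-En4, and list members that moved against their list and were not named by the rule for named genes, were chosen after their values were seen.

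Dgat2 encodes the acyltransferase that completes triacylglycerol synthesis, and Pnpla2 encodes adipose triglyceride lipase, which starts triacylglycerol breakdown. Dgat2 (ENSMUSG00000030747) lies on chromosome 7 from 99153658 to 99182719 on the minus strand in GRCm38, and Pnpla2 (ENSMUSG00000025509) on chromosome 7 from 141455198 to 141460743 on the plus strand. The positions of the enhancers and guides were not used here. Dgat2 was at 286 ± 80.0 TPM in control and 114 ± 12.6 TPM in Dgat2-En4, 39.9% of the control mean. Its log2 fold change was -1.29 (SE 0.17, limma adjusted p = 0.00024), or -1.59 relative to all genes. Pnpla2 was at 842 ± 68.5 TPM in control and 484 ± 46.7 TPM in Pnpla2-En5, 57.4% of the control mean. Its log2 fold change was -0.80 (SE 0.088, limma adjusted p = 9.3e-05), or -1.10 relative to all genes.

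Pnpla2 also fell in Dgat2-En4, where it was not targeted, to 369 ± 14.6 TPM or 43.7% of control (log2 fold change -1.19, limma adjusted p = 6.3e-06, -1.49 relative to all genes). It was lower there than in Pnpla2-En5, by a log2 difference of -0.39 (limma adjusted p = 0.020). Dgat2 in Pnpla2-En5 was at 432 ± 32.6 TPM, 151% of control, with a log2 fold change of 0.63 on the TPM scale (limma adjusted p = 0.014) and 0.33 relative to all genes. That call ended under median-of-ratios scaling, where the log2 fold change was 0.28 (adjusted p = 0.26). Over the 23 alternatives tried it lay between 0.28 and 0.84, with adjusted p from 0.00065 to 0.32. Between the enhancer groups Dgat2 differed by -1.91 (limma adjusted p = 0.00053). In each of these 6 comparisons the 3 libraries of one group all lay above the 3 of the other. The two-sided exact permutation test gave p = 0.1 each time, the smallest p that 3 against 3 libraries allow.

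**Figure D1:**
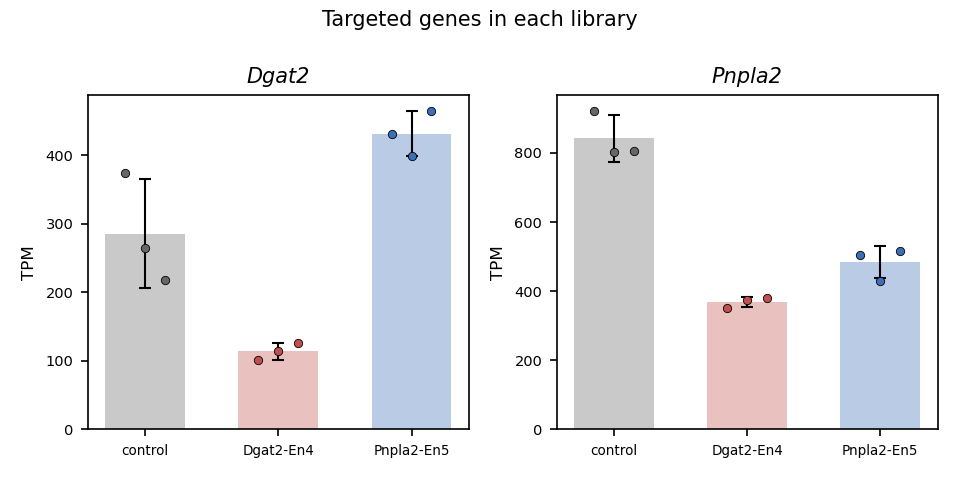
TPM of Dgat2 and Pnpla2 (vertical axes, starting at 0) in the 3 libraries of each group (dots), with the group mean (bar) and SD (error bar). Dgat2 lies between the Dgat2-En4 mean of 114 TPM and the Pnpla2-En5 mean of 432 TPM in control, and Pnpla2 is lower than control in both enhancer groups.

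Against control, the Dgat2-En4 libraries had lower RNA of genes that store, release and oxidize fat, and higher RNA of matrix, preadipocyte, contractile and interferon-response genes. These lists were called by camera at the preset correlation, and no list was called with an estimated correlation (smallest adjusted p = 0.071). Slc2a4, the insulin-regulated glucose transporter, went from 197 ± 11.8 to 59.1 ± 7.95 TPM. Adipoq, which encodes the hormone adiponectin, went from 2673 ± 440.2 to 1286 ± 34.9 TPM, and Pparg, the central transcription factor of fat cells, from 298 ± 34.6 to 163 ± 10.8 TPM. In the other direction, Dlk1, a preadipocyte protein that restrains adipogenesis, went from 159 ± 8.31 to 1317 ± 98.4 TPM, and Lox, a collagen crosslinking enzyme, from 108 ± 3.82 to 1121 ± 52.8 TPM. All 5 changes passed the limma threshold, with changes relative to all genes of -2.02, -1.34, -1.15, 2.75 and 3.07.

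Of 24 mature adipocyte markers, 17 fell and 3 rose (19 and 3 adjusted over the list alone, 20 and 3 after median-of-ratios scaling). Their median change relative to all genes was -1.20 (camera adjusted p = 6.7e-12, and adjusted p = 0.12 with an estimated correlation). The fatty acid carrier Fabp4 (1893 to 951 TPM) and adipsin, encoded by Cfd (3426 to 1674 TPM), were among those that fell. The 3 that rose were the leptin gene Lep (1.96 to 6.35 TPM), Car3 (49.8 to 176 TPM) and Adcy6 (85.9 to 130.0 TPM). Among 18 genes of triacylglycerol synthesis, 11 fell and 1 rose (11 and 1 adjusted over the list alone, 17 and 1 after median-of-ratios scaling), with a median of -1.04 (camera adjusted p = 1.5e-09, and adjusted p = 0.071 with an estimated correlation). Dgat1, the other enzyme with the activity of Dgat2, went from 315 to 174 TPM, and the acyltransferase gene Agpat4 rose (0.61). Of 18 lipolysis genes, 15 fell and 0 rose (16 and 0 adjusted over the list alone, 18 and 0 after median-of-ratios scaling). The lipolysis list includes Pnpla2 and shares genes with the adipocyte markers and the lipid droplet proteins. That list had a median of -1.06 (camera adjusted p = 2.0e-13, and adjusted p = 0.071 with an estimated correlation) and includes Ces1d (-1.77) and Abhd6 (-1.38). Lipid droplet proteins moved both ways on the TPM scale, where 10 fell and 5 rose (10 and 5 adjusted over the list alone, 11 and 1 after median-of-ratios scaling). The droplet coat genes Plin1 (-1.17) and Plin2 (-1.27) fell, and Plin3 rose (0.24). The median over the 16 genes was -0.87 (camera adjusted p = 3.4e-05, and adjusted p = 0.16 with an estimated correlation). The other risers on TPM were Tmem159 (0.064), Hsd17b11 (0.13), Pcyt1a (-0.042) and Rab18 (0.11), none of which was called higher after median-of-ratios scaling.

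Genes of energy metabolism fell as well. In oxidative phosphorylation, 49 of 60 genes fell and 0 rose (49 and 0 adjusted over the list alone, 59 and 0 after median-of-ratios scaling), with a median of -0.79 (camera adjusted p = 6.4e-32, and adjusted p = 0.071 with an estimated correlation). Cytochrome c, encoded by Cycs, went from 338 ± 53.5 to 145 ± 3.68 TPM and the complex I gene Ndufb8 from 107 ± 7.97 to 57.0 ± 1.31 TPM. For the tricarboxylic acid cycle 23 of 25 genes fell and 1 rose (24 and 1 adjusted over the list alone, 24 and 0 after median-of-ratios scaling), median -0.82 (camera adjusted p = 1.1e-19, and adjusted p = 0.098 with an estimated correlation), led by Mdh1 (-1.32) and Pcx (-1.45). The single riser, Idh2, was at 0.049 relative to all genes and was not called after median-of-ratios scaling. In fatty acid oxidation 20 of 25 genes fell and 2 rose (20 and 2 adjusted over the list alone, 23 and 0 after median-of-ratios scaling), with a median of -0.78 (camera adjusted p = 1.9e-14, and adjusted p = 0.10 with an estimated correlation) and the example Decr1 (-1.10). Its risers on TPM, Pdk4 (0.082) and Cpt1a (0.43), lost their call after median-of-ratios scaling. In branched-chain amino acid catabolism 16 of 23 genes fell and 1 rose (17 and 1 adjusted over the list alone, 22 and 1 after median-of-ratios scaling), median -0.80 (camera adjusted p = 1.3e-14, and adjusted p = 0.084 with an estimated correlation). There the transaminase Bcat2 fell (-1.54) and its cytosolic counterpart Bcat1 rose (1.63). Fatty acid synthesis followed, with 12 of 21 genes lower and 2 higher (12 and 2 adjusted over the list alone, 16 and 1 after median-of-ratios scaling) and a median of -0.70 (camera adjusted p = 1.1e-08, and adjusted p = 0.071 with an estimated correlation), and Scd2 (-1.16) fell while Elovl6 (0.75) rose. The second riser on TPM, Hacd3, was at 0.22 and was not called after median-of-ratios scaling. Of 13 mitochondrially encoded genes, 9 fell and 0 rose (9 and 0 adjusted over the list alone, 12 and 0 after median-of-ratios scaling), with a median of -0.75 (camera adjusted p = 5.0e-07, and adjusted p = 0.20 with an estimated correlation). The share of these genes in the libraries differed as given above.

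Extracellular matrix genes rose, with 34 of 39 genes higher and 0 lower (34 and 0 adjusted over the list alone, 33 and 1 after median-of-ratios scaling) and a median of 1.45 (camera adjusted p = 8.0e-12, and adjusted p = 0.084 with an estimated correlation). Besides Lox, Postn went from 143 ± 8.76 to 812 ± 87.0 TPM and Col12a1 from 5.00 ± 0.485 to 42.5 ± 3.21 TPM. Of 19 preadipocyte and anti-adipogenic genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone, 17 and 1 after median-of-ratios scaling), median 1.15 (camera adjusted p = 6.0e-07, and adjusted p = 0.071 with an estimated correlation), among them Pdgfra, a receptor of mesenchymal progenitors (1.87), and the Wnt modulator Sfrp2 (3.07). For myofibroblast and smooth muscle genes 14 of 16 genes rose and 2 fell (14 and 2 adjusted over the list alone, 14 and 2 after median-of-ratios scaling), with a median of 1.25 (camera adjusted p = 0.00036, and adjusted p = 0.19 with an estimated correlation). Cnn2 (2.497) and Tpm1 (2.16) rose, and Myh11 (-1.28) and Des (-1.33) fell. Among 42 interferon-response genes, 39 rose and 0 fell (39 and 0 adjusted over the list alone, 37 and 0 after median-of-ratios scaling), and their median was 1.33 (camera adjusted p = 2.6e-08, and adjusted p = 0.29 with an estimated correlation). Oas1b went from 1.33 ± 0.297 to 14.2 ± 1.73 TPM and Trim30a from 8.20 ± 0.743 to 44.7 ± 2.68 TPM. Inflammatory and NF-kB genes rose, with 14 of 19 genes higher and 1 lower (14 and 1 adjusted over the list alone, 13 and 2 after median-of-ratios scaling) and a median of 1.07 (camera adjusted p = 0.00046, and adjusted p = 0.19 with an estimated correlation), including Csf1 (2.02) and Ptx3 (2.48), and the exception Lcn2 fell (-1.87). Of 44 cell cycle genes, 37 rose and 1 fell (38 and 1 adjusted over the list alone, 20 and 3 after median-of-ratios scaling), median 0.31 (camera adjusted p = 0.00048, and adjusted p = 0.28 with an estimated correlation). Cyclin D1, encoded by Ccnd1, went from 7.75 ± 0.344 to 57.7 ± 7.69 TPM, and Ccne1 fell (-0.70). Among the other cell types that a culture might hold, 5 of 14 macrophage markers reached the tested level, with 3 higher and 0 lower (3 and 0 adjusted over the list alone, 3 and 1 after median-of-ratios scaling) and a median of 0.57 (camera adjusted p = 0.36, and adjusted p = 0.45 with an estimated correlation). Lyz2 went from 0.957 to 6.30 TPM, Aif1 from 0.267 to 2.84 TPM and Cd14 from 4.37 to 8.74 TPM. Fcer1g (adjusted p = 0.10) was at 0.774 and 1.56 TPM and Cd68 (adjusted p = 0.31) at 8.33 and 7.25 TPM. In Pnpla2-En5 there were 4 higher and 0 lower (4 and 0 adjusted over the list alone, 3 and 0 after median-of-ratios scaling).

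**Figure D2:**
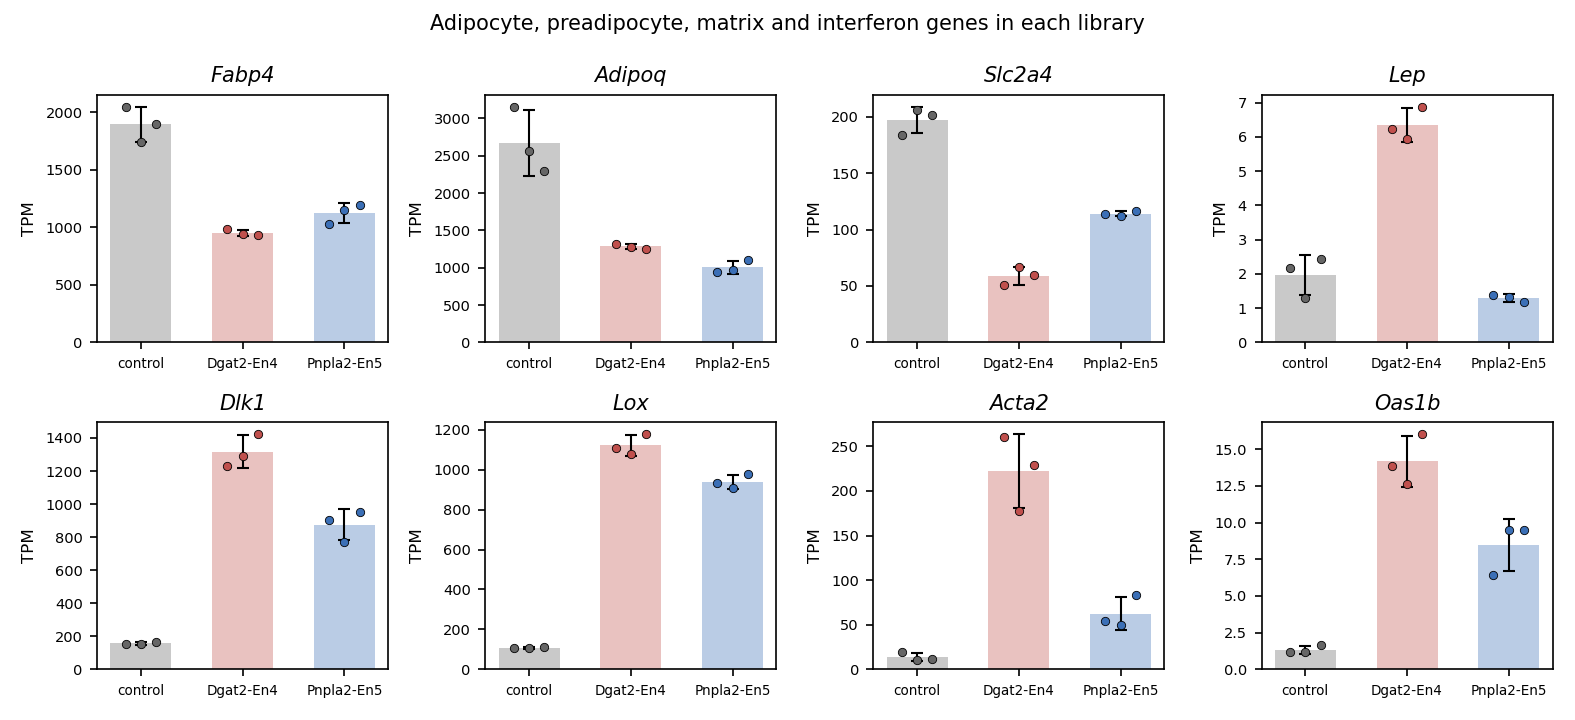
TPM of 8 genes (vertical axes, starting at 0) in the 3 libraries of each group (dots), with the group mean (bar) and SD (error bar). Fabp4, Adipoq and Slc2a4 are lower and Dlk1, Lox, Acta2 and Oas1b higher than control in both enhancer groups, while Lep is higher in Dgat2-En4 at 6.35 TPM.

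Among the single genes that rose most in Dgat2-En4 were the matrix protease Mmp9 (2.07 ± 1.37 to 45.8 ± 4.90 TPM), the smooth muscle actin gene Acta2 (13.8 ± 4.55 to 222 ± 41.6 TPM), the myosin light chain Myl9 (3.27), Sulf2 (3.18), Oasl2 (3.12), Sfrp2 and Lox. Sulf2 shares exonic sequence with Ncoa3, Sfrp2 with Gm26771 and Lox with AC161119.1, and the strand setting of the counting is not stated, so these 3 are less certain. The largest falls were those of Ang5 (27.0 ± 5.16 to 1.52 ± 0.174 TPM), Retnla (35.5 ± 7.75 to 2.70 ± 1.29 TPM), Rprml (-3.22), Ghrh (381 ± 163 to 66.3 ± 32.3 TPM), Ang4 (-2.74) and Pnpla3 (40.9 ± 2.10 to 6.78 ± 0.377 TPM). Ang4 and Ang5 are close paralogs and can share reads, and Pnpla3 overlaps Gm49513. Mir1938, which overlaps Gm7008, and Mir6400 also passed the rule, with means of 9 and 4.67 reads per control library, and Mir6400 was listed at 0 in all 3 Dgat2-En4 libraries. All of these risers and fallers kept their call and direction after median-of-ratios scaling.

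By limma, 9075 genes changed between Dgat2-En4 and control, 7403 higher and 1672 lower (81.6% higher). After median-of-ratios scaling the count was 7781, with 3749 higher and 4032 lower (48.2% higher). On the TPM scale 1776 of the higher and 212 of the lower genes differed at least 2-fold. On the TPM scale the 3 libraries of one group all lay above those of the other for 61.6% of tested genes. By chance this has a probability of 10% for a single gene. The shift common to most genes on that scale can separate groups by itself, and genes are not independent. The 10% is therefore no reference for this share. No list was called with an estimated inter-gene correlation in any of the 3 comparisons.

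Against control, the Pnpla2-En5 libraries also had lower adipocyte and higher matrix and preadipocyte RNA. These lists too were called at the preset correlation, and none with an estimated one (smallest adjusted p = 0.144). Adipoq went from 2673 ± 440.2 to 1006 ± 87.7 TPM, Cfd from 3426 ± 258 to 1239 ± 131 TPM, and the lipase gene Pnpla3 from 40.9 ± 2.10 to 3.84 ± 1.65 TPM. Dlk1 reached 874 ± 94.1 TPM and Lox 939.8 ± 35.4 TPM. Fkbp5, a glucocorticoid-induced chaperone, went from 14.8 ± 1.63 to 62.8 ± 6.20 TPM, and the osteopontin gene Spp1 from 80.5 ± 12.4 to 612 ± 65.7 TPM. All 7 changes passed the limma threshold.

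Of 24 mature adipocyte markers, 15 fell and 3 rose (16 and 3 adjusted over the list alone, 19 and 1 after median-of-ratios scaling), with a median of -1.06 (camera adjusted p = 1.9e-14, and adjusted p = 0.14 with an estimated correlation). Pck1, which supplies glycerol for triacylglycerol, was among those that fell (-2.68). The 3 risers on TPM were Adcy6 (0.42), Car3 (0.85) and Thrsp (0.69), and Car3 and Thrsp lost their call after median-of-ratios scaling. Lipolysis genes fell, with 13 of 18 genes lower and 2 higher (13 and 2 adjusted over the list alone, 16 and 2 after median-of-ratios scaling) and a median of -0.99 (camera adjusted p = 3.9e-11, and adjusted p = 0.14 with an estimated correlation), while Pde3b (0.68) rose. For triacylglycerol synthesis 8 of 18 genes fell and 2 rose (8 and 2 adjusted over the list alone, 11 and 1 after median-of-ratios scaling), median -0.59 (camera adjusted p = 2.8e-06, and adjusted p = 0.14 with an estimated correlation), the risers being Agpat4 (0.84) and Dgat2. Among 16 lipid droplet proteins 8 fell and 4 rose (10 and 4 adjusted over the list alone, 12 and 1 after median-of-ratios scaling), with a median of -0.62 (camera adjusted p = 2.0e-05, and adjusted p = 0.21 with an estimated correlation) and the fall of Cidec (-1.60). The risers Plin3 (0.22), Rab18 (0.19), Tmem159 (0.12) and Hsd17b11 (0.29) kept no call after median-of-ratios scaling except Plin3. In oxidative phosphorylation 31 of 60 genes fell and 2 rose (31 and 2 adjusted over the list alone, 54 and 0 after median-of-ratios scaling), median -0.54 (camera adjusted p = 4.9e-20, and adjusted p = 0.14 with an estimated correlation), with Cycs at -1.31 and Ndufb8 at -0.95. Its risers on TPM, Ndufa6 (-2.4e-05) and Atp5j (0.052), had no call after median-of-ratios scaling. Tricarboxylic acid cycle genes fell, with 12 of 25 genes lower and 1 higher (12 and 1 adjusted over the list alone, 23 and 1 after median-of-ratios scaling) and a median of -0.48 (camera adjusted p = 1.0e-10, and adjusted p = 0.23 with an estimated correlation), and Idh2 rose (0.27). Of 13 mitochondrially encoded genes 13 fell and 0 rose (13 and 0 adjusted over the list alone, 13 and 0 after median-of-ratios scaling), with a median of -0.93 (camera adjusted p = 3.0e-12, and adjusted p = 0.16 with an estimated correlation), in libraries whose mitochondrial share was lower as given above.

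Fatty acid oxidation had 7 of 25 genes lower and 1 higher (5 and 1 adjusted over the list alone, 19 and 1 after median-of-ratios scaling) and a median of -0.46 (camera adjusted p = 2.2e-07, and adjusted p = 0.23 with an estimated correlation), with Pdk4, which restrains glucose oxidation, as the riser (0.89). Branched-chain amino acid catabolism had 8 of 23 genes lower and 1 higher (8 and 1 adjusted over the list alone, 17 and 1 after median-of-ratios scaling), median -0.39 (camera adjusted p = 2.0e-06, and adjusted p = 0.23 with an estimated correlation), and Bcat1 again rose (1.08). Fatty acid synthesis genes moved both ways on the TPM scale, where 7 fell and 5 rose (7 and 5 adjusted over the list alone, 13 and 2 after median-of-ratios scaling), with a median of -0.43 (camera adjusted p = 0.00010, and adjusted p = 0.14 with an estimated correlation) over 21 genes. Fads2 (-0.89) fell and Elovl6 (0.40) rose. The other risers were Hacd3 (0.31), Thrsp, Elovl5 (0.085) and Srebf1 (-0.032), of which only Hacd3 kept its call after median-of-ratios scaling.

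Matrix genes rose, with 35 of 39 genes higher and 1 lower (35 and 1 adjusted over the list alone, 30 and 2 after median-of-ratios scaling) and a median of 0.97 (camera adjusted p = 2.4e-10, and adjusted p = 0.14 with an estimated correlation), and Mmp13 (-0.86) fell. Vcan (1.49) and Bgn (1.30) were among the risers. Of 19 preadipocyte and anti-adipogenic genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone, 15 and 0 after median-of-ratios scaling), median 0.85 (camera adjusted p = 2.2e-06, and adjusted p = 0.14 with an estimated correlation), with Pdgfra at 1.75 and Ly6a at 1.89. For myofibroblast and smooth muscle genes 14 of 16 genes rose and 1 fell (14 and 2 adjusted over the list alone, 12 and 2 after median-of-ratios scaling), with a median of 0.91 (camera adjusted p = 0.0012, and adjusted p = 0.25 with an estimated correlation), including Mylk (1.54), and Des (-0.89) fell. Inflammatory and NF-kB genes rose, with 16 of 19 genes higher and 0 lower (16 and 0 adjusted over the list alone, 12 and 0 after median-of-ratios scaling), median 0.48 (camera adjusted p = 0.00019, and adjusted p = 0.23 with an estimated correlation), Csf1 at 1.39 among them. Interferon-response genes had 28 of 42 genes higher and 2 lower (28 and 2 adjusted over the list alone, 21 and 3 after median-of-ratios scaling) and a median of 0.52 (camera adjusted p = 0.025, and adjusted p = 0.70 with an estimated correlation). Mx1 went from 1.57 ± 0.429 to 12.0 ± 3.23 TPM, and Psmb9 (-0.88) and Ifi27 (-0.61) fell. Among 20 glucocorticoid-responsive genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, 10 and 1 after median-of-ratios scaling), with a median of 0.41 (camera adjusted p = 0.0047, and adjusted p = 0.25 with an estimated correlation), including Tsc22d3 (1.06) and Glul (0.84), and Angptl4 (-1.06) fell. Cytosolic ribosomal protein genes rose on the TPM scale, with 67 of 70 genes higher and 0 lower (68 and 0 adjusted over the list alone, 31 and 2 after median-of-ratios scaling) and a median of 0.21 (camera adjusted p = 6.2e-09, and adjusted p = 0.25 with an estimated correlation). Cell cycle genes were not called as a list (camera adjusted p = 0.64, and adjusted p = 0.89 with an estimated correlation), and 15 of 44 genes rose and 2 fell (14 and 2 adjusted over the list alone, 4 and 13 after median-of-ratios scaling).

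**Figure D3:**
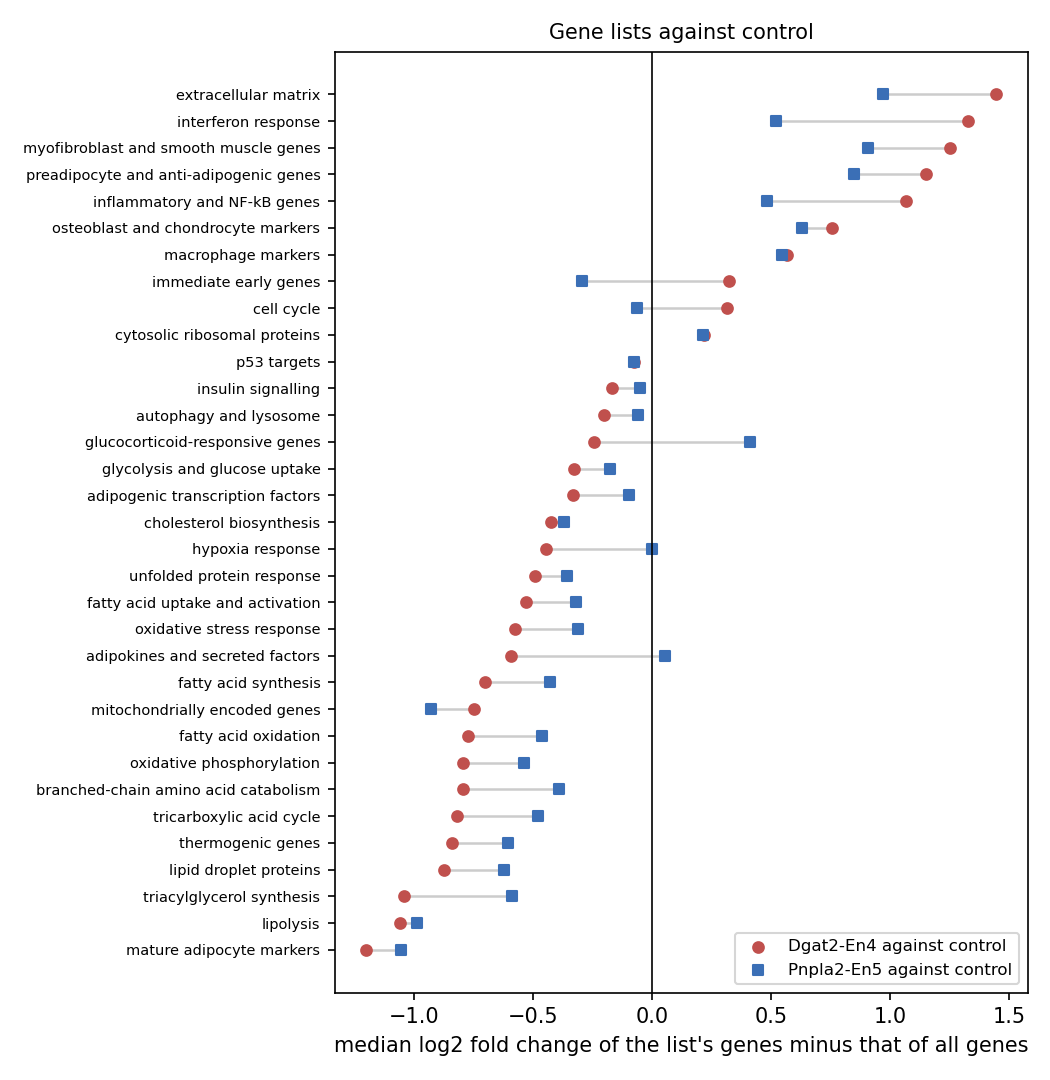
Median log2 fold change of each gene list minus that of all tested genes (horizontal axis) for Dgat2-En4 against control (circles) and Pnpla2-En5 against control (squares), 1 line per list. Matrix genes lie highest in both, at 1.45 and 0.97, and mature adipocyte markers lowest, at -1.20 and -1.06.

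Among the genes that rose most in Pnpla2-En5 were Igfbp3, which binds insulin-like growth factors (11.3 ± 1.84 to 154 ± 26.3 TPM), Slc6a14 (2.93), Gdpd2 (2.83), Lox (2.81), Ctla2a (2.79) and the angiotensin receptor gene Agtr2 (12.4 ± 3.56 to 106 ± 15.02 TPM). Gdpd2 overlaps Gm14866, and Ctla2a overlaps Gm49391 and Gm49393 and has close paralogs. Pnpla3 (-3.48), Retnla (-3.47), Rprml (-3.30), the fatty acid receptor gene Ffar2 (-2.71), Pck1 and Rasd1 (-2.68) fell most. Mir1938 and the mitochondrial tRNA gene mt-Tq were listed at 0 in all 3 Pnpla2-En5 libraries, with means of 9 and 4.67 reads in control. All of these risers and fallers kept their call and direction after median-of-ratios scaling.

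In total 8461 genes changed between Pnpla2-En5 and control by limma, 7467 higher and 994 lower (88.3% higher). With median-of-ratios scaling 6413 changed, 3241 higher and 3172 lower (50.5% higher). At least 2-fold changes numbered 1295 higher and 155 lower on the TPM scale. On that scale 58.9% of tested genes had fully separated groups, a share with the same limit as in Dgat2-En4.

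Both comparisons called 6069 genes higher, 796 lower and 67 in opposite directions. Independent lists of these sizes would share 3382.6 and 101.7 genes. After median-of-ratios scaling the shared counts were 2544 higher, 2655 lower and 45 opposite, against 743.5 and 782.6 for independent lists. In 100 simulations of unchanged groups, all 9 libraries were drawn anew around the control means, with noise independent between genes. These shared 0 genes each time, which the setting made likely, since no gene was changed and few could be called. The 0 is therefore no measure of the overlap to be expected here. Across genes, which are not independent replicates, the fold changes correlated with Pearson's r of 0.805, against 0.500 in the simulations. Their covariance was 0.269 against a simulated 0.0282. The 3 control libraries cannot be split into parts of at least 2 each. A departure of these libraries common to many genes is not in the simulations, so part of the excess may still come from the shared controls.

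Compared directly, the Dgat2-En4 libraries had higher interferon, cell cycle and immediate early gene RNA than the Pnpla2-En5 libraries, and lower RNA of nuclear-encoded mitochondrial metabolism and of glucocorticoid-responsive genes. Again the lists were called at the preset correlation only (smallest adjusted p = 0.157 with an estimated one). Among 42 interferon-response genes, 32 were higher and 0 lower (41 and 0 adjusted over the list alone, 32 and 0 after median-of-ratios scaling), with a median of 0.74 (camera adjusted p = 4.5e-19, and adjusted p = 0.16 with an estimated correlation). Usp18 was at 18.3 ± 2.15 against 8.06 ± 1.79 TPM and Irf9 at 20.5 ± 1.37 against 11.8 ± 1.38 TPM. Of 44 cell cycle genes 30 were higher and 0 lower (34 and 0 adjusted over the list alone, 29 and 0 after median-of-ratios scaling), median 0.40 (camera adjusted p = 4.9e-14, and adjusted p = 0.16 with an estimated correlation), with the proliferation marker Mki67 at 21.3 ± 2.74 against 13.3 ± 0.677 TPM. For immediate early genes 13 of 23 genes were higher and 0 lower (14 and 1 adjusted over the list alone, 12 and 0 after median-of-ratios scaling), with a median of 0.41 (camera adjusted p = 6.0e-08, and adjusted p = 0.16 with an estimated correlation). Egr1 was at 167 ± 10.9 against 42.2 ± 6.54 TPM, with control at 50.9 ± 8.37. Matrix genes had 19 of 39 genes higher and 1 lower (23 and 4 adjusted over the list alone, 18 and 1 after median-of-ratios scaling), median 0.25 (camera adjusted p = 6.0e-08, and adjusted p = 0.16 with an estimated correlation), and Ccn1 (2.20) and Thbs1 (1.36) were higher while Col4a2 (-0.37) was lower.

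In oxidative phosphorylation 29 of 60 genes were lower and 0 higher (41 and 0 adjusted over the list alone, 31 and 0 after median-of-ratios scaling), with a median of -0.26 (camera adjusted p = 3.7e-17, and adjusted p = 0.16 with an estimated correlation), such as Uqcrq at 201 ± 15.8 against 289 ± 20.2 TPM. Tricarboxylic acid cycle genes followed with 20 of 25 genes lower and 0 higher (22 and 0 adjusted over the list alone, 20 and 0 after median-of-ratios scaling), median -0.36 (camera adjusted p = 5.0e-14, and adjusted p = 0.16 with an estimated correlation), including Pdhb (-0.64). Mitochondrially encoded genes went the other way, with 2 of 13 genes higher and 0 lower (2 and 0 adjusted over the list alone, 2 and 0 after median-of-ratios scaling) and a median of 0.25 (camera adjusted p = 0.033, and adjusted p = 0.56 with an estimated correlation). Of 20 glucocorticoid-responsive genes 15 were lower and 1 higher (15 and 1 adjusted over the list alone, 15 and 1 after median-of-ratios scaling), with a median of -0.73 (camera adjusted p = 1.3e-10, and adjusted p = 0.16 with an estimated correlation). Glul was at 198 ± 7.76 against 418 ± 13.4 TPM, and Sgk1 (0.60) was higher. In branched-chain amino acid catabolism 13 of 23 genes were lower and 1 higher (20 and 1 adjusted over the list alone, 14 and 1 after median-of-ratios scaling), median -0.35 (camera adjusted p = 1.6e-11, and adjusted p = 0.16 with an estimated correlation), with Bcat2 at 122 ± 8.10 against 244 ± 13.9 TPM. Mature adipocyte markers were not called as a list (camera adjusted p = 0.41, and adjusted p = 0.82 with an estimated correlation), and 5 of 24 genes were lower and 5 higher (8 and 7 adjusted over the list alone, 5 and 5 after median-of-ratios scaling). Lep (1.68) and Sncg (0.84) were higher, and Slc2a4 (-0.95) and Mrap (-0.96) lower, in Dgat2-En4.

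The direct comparison called 2387 genes by limma, 1095 higher and 1292 lower in Dgat2-En4, and 1092 and 1317 after median-of-ratios scaling. The count fell to 1313, 1816 and 1244 without Dgat2-En4 replicates 1, 2 and 3. Without Pnpla2-En5 replicates 1, 2 and 3 it fell to 1284, 1632 and 1357. These fits have fewer libraries in a compared group, so whether calls rested on single libraries cannot be told from them. The count was 930 at an adjusted p under 0.01. Groups were fully separated for 39.1% of genes. Among the lower genes with the largest differences were Ctla2a (-2.09), the iron-binding protein gene Lcn2 (21.9 ± 3.21 against 93.2 ± 7.43 TPM), Folh1 (-2.02), Ang5 (-1.99) and Dgat2, with the short RNAs Snord7 and Mir196a-1 at means of 13 and 9.67 reads per Pnpla2-En5 library. Snord7 lost its call after median-of-ratios scaling (adjusted p = 0.062). All 8 highest genes were short RNAs with few reads, which polyA libraries sample poorly. They were mt-Tt and mt-Tq, listed at 0 in Pnpla2-En5, and mt-Tl1, Mir322, Mir6976, Mir7647, Mir143 and Mir5618. Of these mt-Tl1 had the most reads, a mean of 141 per Dgat2-En4 library against 22.7.

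Genes near the targeted genes on chromosome 7 were examined because a repressor can act on more than 1 gene. Near Pnpla2, Cd151 (6.65 kb away), Polr2l (11.1 kb) and Taldo1 (52.2 kb) fell in both enhancer groups, by -0.86, -0.69 and -1.29 in Dgat2-En4 and by -0.61, -0.74 and -0.64 in Pnpla2-En5. Slc25a22 (17.3 kb) fell in Dgat2-En4 (-0.83). In Pnpla2-En5 it was at -0.53, not called on the TPM scale (adjusted p = 0.12) but lower after median-of-ratios scaling (adjusted p = 0.0070). Taldo1 and Cd151 were lower in Dgat2-En4 than in Pnpla2-En5, by -0.66 and -0.25. Farther away, Irf7 (1.12 and 0.54) and Lsp1 (2.10 and 1.40) rose in both groups, and Irf7 overlaps Phrf1. On the side of Dgat2, the collagen chaperone gene Serpinh1 (163 kb) rose by 0.89 and 0.70. Gdpd5 (199 kb), Lrrc32 (651 kb) and Capn5 (975 kb) also rose in both groups. Tsku, 792 kb from Dgat2, rose in Pnpla2-En5 (0.35), as did Rassf7, 237 kb from Pnpla2 (0.46). Each of these calls kept its direction and stayed a call after median-of-ratios scaling. Other genes close to Pnpla2 went the other way on the TPM scale and lost their call after that scaling: Tspan4 (14.5 kb, log2 fold change 0.65, adjusted p = 0.0066) and Pidd1 (11.2 kb, 0.46, adjusted p = 0.033) were higher in Dgat2-En4, and Rplp2 (3.61 kb, 0.25, adjusted p = 0.018) and Chid1 (32.4 kb, 0.29, adjusted p = 0.0046) in Pnpla2-En5. The gene nearest to Pnpla2, Cracr2b (0.351 kb), was not called on the TPM scale in any comparison and was lower in Pnpla2-En5 after median-of-ratios scaling (log2 fold change -0.45, adjusted p = 0.049). Relative to all genes Cracr2b was at -0.48 in Dgat2-En4 and -0.51 in Pnpla2-En5. The log2 difference between these groups was 0.031 (limma adjusted p = 0.92), so its level was not particular to Pnpla2-En5. The gene nearest to Dgat2, Uvrag (12.5 kb), was not called on the TPM scale in any comparison. Relative to all genes it was at -0.28 in Dgat2-En4 and -0.25 in Pnpla2-En5. Arrb1, 353 kb from Dgat2, was at -0.38 and -0.16, and was not called against control on the TPM scale. On that scale the median gene rose by 0.299 in Dgat2-En4 and 0.3002 in Pnpla2-En5. The missing calls therefore do not show that Uvrag and Arrb1 were unchanged relative to all genes. As lists, the neighbours of Dgat2 had 12 of 16 genes higher and 0 lower (12 and 0 adjusted over the list alone, 4 and 3 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.086, and adjusted p = 0.39 with an estimated correlation), and the neighbours of Pnpla2 had 10 of 25 genes higher and 3 lower (10 and 3 adjusted over the list alone, 3 and 6 after median-of-ratios scaling) in Pnpla2-En5 (camera adjusted p = 0.81, and adjusted p = 0.89 with an estimated correlation) and 9 of 25 genes higher and 4 lower (9 and 4 adjusted over the list alone, 3 and 13 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.22, and adjusted p = 0.47 with an estimated correlation). Neither list was called by camera in any comparison.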

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

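The tests of causes in this part, and the bounds they were judged by, were chosen after the results were seen, and the tests and bounds for the adipocyte markers were revised after their values were known. The values given are differences between the enhancer groups, Dgat2-En4 minus Pnpla2-En5 on the log2 scale, that passed limma for genes or camera for lists, so the effects of the enhancer groups against control differed. Dgat2 differed by -1.91 and Pnpla2 by -0.39.

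Mature adipocyte markers were lower in both enhancer groups by camera at the preset correlation, but were not called with an estimated one (adjusted p = 0.12 in Dgat2-En4 and 0.144 in Pnpla2-En5). After median-of-ratios scaling Dgat2 was at -1.92 (SE 0.18) in Dgat2-En4 against Pnpla2-En5, where the markers had a median of -0.11 (SD 0.75), the lowest was Thrsp at -1.29 and 0 of 24 were as low as Dgat2. Relative to all genes Dgat2 was at 0.33 in Pnpla2-En5 against control while the markers had a median of -1.06. A fall shared with the adipocyte markers is therefore argued against as the whole cause of the lower Dgat2 between the enhancer groups. Against control Dgat2 was at -1.64 (SE 0.18) and the markers at a median of -1.25 (SD 0.85), with 2 of 24 as low as Dgat2, so there its fall cannot be told apart from theirs, as it lies within their spread. For Pnpla2 in Pnpla2-En5 against control, at -1.15 (SE 0.092) beside a marker median of -1.10, 9 of 24 markers were at least as low, so its fall may be part of the lower adipocyte expression, and it was not lower than in Dgat2-En4. A lower share of differentiated cells could account for the fall of the markers, but 3 of them (Car3, Lep and Adcy6) were higher in Dgat2-En4 under both scalings and 1 (Adcy6) in Pnpla2-En5. Without undifferentiated cells here to show which markers other cells express, that explanation cannot be told apart from a change within the cells, and direct effects of the enhancers and differences between the transduced cell pools stay open, as untested.

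Interferon-response genes were higher in Dgat2-En4 than in control and than in Pnpla2-En5 by camera at the preset correlation, but were not called with an estimated one (adjusted p = 0.29 and 0.16). Some macrophage markers rose with them, and the 5 tested had 3 higher and 0 lower (3 and 0 adjusted over the list alone, 3 and 1 after median-of-ratios scaling). Aif1 went from 0.267 to 2.84 TPM, Lyz2 from 0.957 to 6.30 TPM and Cd14 from 4.37 to 8.74 TPM, and in Pnpla2-En5 4 of the 5 were higher. Macrophages are argued against as the whole cause by the median of all 14 markers, 0.218 TPM in Dgat2-En4 against 17.1 TPM for the interferon list, with median rises over control of 0.044 and 11.5 TPM. The 9 markers under the tested level reached at most 0.406 TPM, with Ptprc at 0.0020 TPM and Tyrobp listed at 0. A small share of macrophages is not excluded by this, and other immune cells were not tested. Scaling between libraries is argued against as the whole cause by the 37 of 42 genes still higher after median-of-ratios scaling. A response to the guides or to the particular transduced cell pool is a candidate explanation that was not tested, since these go with the group. The labels' protocols give the same infection and selection for all groups, control included.

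Lists higher in Dgat2-En4, as medians relative to all genes, were interferon response at 0.74, inflammatory and NF-kB genes at 0.44, immediate early genes at 0.41, cell cycle at 0.40, myofibroblast and smooth muscle genes at 0.34, preadipocyte genes at 0.26, extracellular matrix at 0.25 and mitochondrially encoded genes at 0.25. Lists lower there were glucocorticoid-responsive genes at -0.73, adipokines at -0.46, fatty acid oxidation at -0.37, tricarboxylic acid cycle at -0.36, branched-chain amino acid catabolism at -0.35, adipogenic transcription factors at -0.34, fatty acid synthesis at -0.30, hypoxia response at -0.29, oxidative phosphorylation at -0.26, triacylglycerol synthesis at -0.26 and lipolysis at -0.26. Smaller differences were those of thermogenic genes at -0.22, oxidative stress response at -0.20, unfolded protein response at -0.19, glycolysis at -0.18, fatty acid uptake at -0.091 and cholesterol biosynthesis at -0.084. None of these lists was called with an estimated correlation, where adjusted p lay between 0.16 and 0.56.

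Among single genes the difference was 1.84 for Acta2, 1.84 for Myl9, 1.36 for Oasl2, 1.36 for Pck1, 1.10 for Sfrp2, 1.01 for Mmp9, 0.82 for Ffar2, 0.74 for Sulf2, 0.71 for Lsp1 and 0.25 for Lox. It was -2.09 for Ctla2a, -1.99 for Ang5, -1.60 for Ghrh, -1.14 for Igfbp3, -1.12 for Slc6a14, -1.01 for Ang4, -0.65 for Taldo1, -0.58 for Rassf7, -0.48 for Tsku, -0.25 for Cd151 and -0.21 for Rnh1. For mt-Tq, listed at 0 in Pnpla2-En5, and Mir6400, listed at 0 in Dgat2-En4, the fitted values of 3.08 and -2.19 depend on the pseudocount and are no fold.

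The 6 libraries of each comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split, fitted on these 6 libraries, gave 8447 genes for Dgat2-En4 against control, where the highest other split gave 0. It gave 7872 for Pnpla2-En5 against control, with 0 in the highest other, and 2866 between the enhancer groups, with 1 in the highest other. In each comparison 1 of the 10 splits, the real one, gave as many. Every other split mixes the compared groups, so a difference between them widens the spread and keeps calls few. The low counts of the other splits are therefore no measure of chance.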

How the results depend on the processing

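The voom fit on recovered reads, and the replicate block with median-of-ratios scaling, were chosen after seeing the data, and the planned test on raw counts was not run because the tables hold TPM. Of 92 values for the targeted genes 86 kept call and direction, of 100 gene counts 91 stayed within 1.5 times, and of 75 list counts 72. These counts compare totals, not which genes were called. Of the 9075 genes called in Dgat2-En4, 5421 were called in the same direction under median-of-ratios scaling and 50 in the opposite one. Of the 8461 in Pnpla2-En5 these were 4235 and 43. For 448 other named results, 9761 of 10247 values kept call and direction, 439 lost the call and 47 turned, and 370 results kept both throughout. For 105 list results, 2336 of 2406 values kept, 35 lost and 35 gained a call. With an estimated correlation 0 lists were called in each comparison, against 26, 24 and 25 at the preset, and fry called 31, 26 and 26, of which 22, 16 and 24 were also called by camera at the preset, in the same direction. Median, mean and camera's direction differed in sign only for lists that camera did not call. Fry works on changes not set against all genes. In Dgat2-En4 it called 4 lists higher that camera had as lower without a call (autophagy and lysosome, glucocorticoid-responsive genes, insulin signalling and neighbours of Pnpla2). In Pnpla2-En5 it called 5 such lists higher (adipogenic transcription factors, adipokines, cell cycle, p53 targets and neighbours of Pnpla2), and cholesterol biosynthesis, glycolysis and immediate early genes, which camera called lower, were higher by fry without a call (adjusted p = 0.73, 0.54 and 0.48). The cause of changes was not tested unless stated.

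Dgat2 in Pnpla2-En5 lost its call under trimmed-mean scaling (0.30, adjusted p = 0.22), median-of-ratios (0.28, adjusted p = 0.26), quantile (0.38, adjusted p = 0.16), rescaling without mitochondrial and top genes (0.37, adjusted p = 0.14), voom (0.30, adjusted p = 0.10) and the block with median-of-ratios scaling (0.28, adjusted p = 0.32), out of a range of 0.00065 to 0.32. A required fold of 2, stricter by construction, left 1988 genes in Dgat2-En4, 1450 in Pnpla2-En5, 226 between them and 1078 in both, and an adjusted p under 0.01 left 930 between them. Leaving out each library gave -1.46 to -1.07 for Dgat2 and -1.22 to -1.12 for Pnpla2 in Dgat2-En4, and 0.45 to 0.84 and -0.85 to -0.72 in Pnpla2-En5. Gene counts were 7880 to 8948, 7105 to 8344, 1244 to 2956 between the enhancer groups and 5704 to 6723 in both, and list counts 26 to 27, 22 to 24 and 21 to 26. The direct count was 1313, 1816 and 1244 without Dgat2-En4 replicates 1, 2 and 3, where fewer samples are left. Without Pnpla2-En5 replicates 1, 2 and 3 it was 1284, 1632 and 1357, again with fewer samples.

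The replicate numbers did not pair the libraries: 0 of 9 same-numbered pairs correlated over 0.1 (-0.042 to 0.056), and not every library correlated best with its own number. With the replicate block 8820, 8154 and 1951 genes were called, and 6591 in both.

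The turned values among the named results, all of neighbours of the targeted genes, arose under other scalings and voom. In Dgat2-En4 Spcs2, Ap2a2 and Ctsd were at -0.17, -0.012 and -0.095 under trimmed-mean scaling, -0.17, -0.0097 and -0.093 under median-of-ratios scaling with or without the replicate block, and -0.16, -0.0029 and -0.084 under voom. Spcs2 was at -0.087 under quantile normalization, with Acer3 at -0.081 and Neu3 at -0.014, and at -0.044 after rescaling. In Pnpla2-En5 Spcs2, Chid1, Rnf169, Rplp2, Rnh1 and Tollip were at -0.054, -0.018, -0.016, -0.075, -0.038 and -0.11 under trimmed-mean scaling. They were at -0.071, -0.033, -0.030, -0.091, -0.054 and -0.12 under median-of-ratios scaling with or without the block, and -0.055, -0.020, -0.010, -0.072, -0.036 and -0.11 under voom. Quantile normalization gave -0.026 for Spcs2, -0.051 for Chid1, -0.084 for Rnf169, -0.078 for Rplp2 and -0.093 for Tollip, and rescaling -0.0016 for Rplp2 and -0.037 for Tollip. Depth limits the short RNAs, several of which rest on under 10 reads per library.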

Other observations

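Further gene lists are given here, with changes relative to all genes. Even at its preset correlation camera did not call immediate early genes, osteoblast and chondrocyte markers, insulin signalling, autophagy and lysosome genes or p53 targets in Dgat2-En4, nor adipogenic transcription factors, osteoblast and chondrocyte markers, insulin signalling, autophagy and lysosome genes, p53 targets or hypoxia genes in Pnpla2-En5, so the counts and members given for these are no call of the list. Adipogenic transcription factors in Dgat2-En4 had 6 of 22 genes lower and 4 higher (6 and 4 adjusted over the list alone, 13 and 2 after median-of-ratios scaling), with a median of -0.33 (camera adjusted p = 0.0019, and adjusted p = 0.16 with an estimated correlation), and Klf15 fell (-1.62) while Klf4 rose (1.03). Thermogenic genes had 8 of 17 genes lower and 2 higher (9 and 2 adjusted over the list alone, 12 and 2 after median-of-ratios scaling) and -0.84 in Dgat2-En4 (camera adjusted p = 3.0e-06, and adjusted p = 0.075 with an estimated correlation), and 8 of 17 genes lower and 2 higher (8 and 2 adjusted over the list alone, 10 and 2 after median-of-ratios scaling) and -0.60 in Pnpla2-En5 (camera adjusted p = 3.7e-05, and adjusted p = 0.14 with an estimated correlation), with Elovl3 at -2.003 and -1.59. Of 24 listed thermogenic genes 17 reached the tested level, and Ucp1, Prdm16 and Dio2 were among those that did not. Immediate early genes had 16 of 23 genes higher and 3 lower (16 and 4 adjusted over the list alone, 12 and 4 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.11, and adjusted p = 0.50 with an estimated correlation), where Egr1 rose (1.41), and a median of -0.29 (camera adjusted p = 0.0054, and adjusted p = 0.34 with an estimated correlation) in Pnpla2-En5, where 7 of 23 genes rose and 5 fell (7 and 5 adjusted over the list alone, 4 and 10 after median-of-ratios scaling) and Atf3 fell (-1.91). Cholesterol synthesis genes in Pnpla2-En5 had 7 of 24 genes lower and 5 higher (7 and 5 adjusted over the list alone, 16 and 3 after median-of-ratios scaling), with a median of -0.37 (camera adjusted p = 0.00064, and adjusted p = 0.23 with an estimated correlation), yet Sqle (0.94) and Cyp51 (0.94) rose. In Dgat2-En4 they had 10 of 24 genes lower and 3 higher (10 and 3 adjusted over the list alone, 18 and 0 after median-of-ratios scaling) (camera adjusted p = 2.3e-05, and adjusted p = 0.12 with an estimated correlation), and Insig1 fell (-0.93). The unfolded protein response had 12 of 26 genes lower and 2 higher (12 and 2 adjusted over the list alone, 25 and 1 after median-of-ratios scaling) in Dgat2-En4, median -0.49 (camera adjusted p = 3.4e-08, and adjusted p = 0.071 with an estimated correlation), with Xbp1 at -0.95, and 7 lower and 6 higher (7 and 6 adjusted over the list alone, 16 and 2 after median-of-ratios scaling) in Pnpla2-En5, median -0.36 (camera adjusted p = 0.00099, and adjusted p = 0.23 with an estimated correlation). Oxidative stress genes had 13 of 24 genes lower and 6 higher (13 and 6 adjusted over the list alone, 17 and 1 after median-of-ratios scaling), median -0.58 (camera adjusted p = 2.1e-06, and adjusted p = 0.11 with an estimated correlation), in Dgat2-En4 and 6 lower and 4 higher (6 and 4 adjusted over the list alone, 15 and 1 after median-of-ratios scaling), median -0.31 (camera adjusted p = 0.00053, and adjusted p = 0.23 with an estimated correlation), in Pnpla2-En5, and Hmox1 fell in both groups (-1.53 and -1.87).

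Osteoblast and chondrocyte markers had 5 of 7 genes higher and 1 lower (5 and 1 adjusted over the list alone, 4 and 1 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.33, and adjusted p = 0.40 with an estimated correlation) and 6 of 7 genes higher and 1 lower (6 and 1 adjusted over the list alone, 5 and 1 after median-of-ratios scaling) in Pnpla2-En5 (camera adjusted p = 0.15, and adjusted p = 0.25 with an estimated correlation). Sox9 (1.72 and 0.999) and Spp1 (1.57 and 2.62) rose in both, and Alpl fell (-1.40 and -1.17). In insulin signalling 10 of 21 genes rose and 6 fell (10 and 6 adjusted over the list alone, 5 and 11 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.52, and adjusted p = 0.56 with an estimated correlation), and Igf1 rose (1.94). Autophagy and lysosome genes had 15 of 31 genes higher and 5 lower (15 and 6 adjusted over the list alone, 7 and 16 after median-of-ratios scaling) there (camera adjusted p = 0.57, and adjusted p = 0.80 with an estimated correlation). P53 targets had 10 of 20 genes higher and 2 lower (10 and 2 adjusted over the list alone, 5 and 7 after median-of-ratios scaling) (camera adjusted p = 0.96, and adjusted p = 0.96 with an estimated correlation), and Plk2 rose (1.46). Hypoxia genes had 8 of 23 genes lower and 4 higher (8 and 4 adjusted over the list alone, 14 and 3 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.00036, and adjusted p = 0.38 with an estimated correlation) and 9 of 23 genes higher and 3 lower (12 and 3 adjusted over the list alone, 5 and 8 after median-of-ratios scaling) in Pnpla2-En5 (camera adjusted p = 0.60, and adjusted p = 0.89 with an estimated correlation), with P4ha1 at 0.86 and 1.05. Glycolysis genes had 9 of 22 genes lower and 5 higher (9 and 5 adjusted over the list alone, 13 and 3 after median-of-ratios scaling) in Dgat2-En4 (camera adjusted p = 0.00036, and adjusted p = 0.28 with an estimated correlation), with Hk2 at -1.27. In Pnpla2-En5 they had 7 higher and 6 lower (7 and 6 adjusted over the list alone, 2 and 10 after median-of-ratios scaling) and a median of -0.18 (camera adjusted p = 0.016, and adjusted p = 0.49 with an estimated correlation). Ribosomal protein genes had 63 of 70 genes higher and 1 lower (64 and 1 adjusted over the list alone, 29 and 4 after median-of-ratios scaling), median 0.22 (camera adjusted p = 3.3e-07, and adjusted p = 0.28 with an estimated correlation), in Dgat2-En4 and 67 higher and 0 lower (68 and 0 adjusted over the list alone, 31 and 2 after median-of-ratios scaling), median 0.21 (camera adjusted p = 6.2e-09, and adjusted p = 0.25 with an estimated correlation), in Pnpla2-En5.

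More genes were higher than lower against control on the TPM scale, 81.6% of changed genes in Dgat2-En4 and 88.3% in Pnpla2-En5. These tests were chosen after that was seen. Lower depth of the control libraries is argued against as the whole cause, since 78.5% and 88.0% of changed genes with a mean of 10 TPM or more were higher too. A scale difference common to most genes is a candidate explanation, since the medians of the 4 classes of genes by mean TPM spanned a range of only 0.109 in Dgat2-En4 and 0.023 in Pnpla2-En5. Whether the mitochondrial and the 20 most abundant genes set that scale cannot be told apart: leaving them out lowered the median log2 fold change of all genes from 0.2986 to 0.115 in Dgat2-En4 and from 0.3002 to 0.089 in Pnpla2-En5, as if they set part of it, but still left 62.6% and 63.7% of changed genes higher, and a change in total RNA per cell was not tested.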
